A study of Rattus norvegicus with 9 samples.

How the data were processed

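The intensity values were used as deposited by the authors. Per the labels the samples were total RNA of rat lung, and the titles and descriptions gave the way of breathing, the oxygen level and the letter of each sample. The values table held 8799 probe sets on 9 arrays. That the values were scaled to a common trimmed mean was read from the values themselves, whose 2% trimmed means lay within 5% of 801 on every array. The software that made the values, the scanner settings and the procedure for RNA and labelling were not given in the sources used here. No detection calls, probe intensities or raw files were among the sources, so no summary of the probes was repeated.

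The 59 control probe sets were left out, which left 8740. Values below 0 were set to 0, and log2(value + 40) was taken, the offset being 5% of the trimmed mean. The 2 arrays with the titles of the letter b sample of mechanical ventilation with 100% oxygen were averaged on the log2 scale and counted as 1 sample. The 40% of probe sets with the lowest mean were not tested, which left 5244 probe sets that stood for 3181 genes. A further 1555 genes had their brightest probe set below that limit and were not tested. No further scaling between arrays was done in the fit reported. Levels in the text are means of the deposited intensities, not of logs.

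A group-means model over the 8 samples was fitted with limma 3.58.1 in R 4.3.3, with eBayes and a trend of the variance on the mean. There were 4 residual degrees of freedom. The 8 contrasts were ventilation and oxygen, each averaged over the other factor and within each level of it, their interaction, and the pair in which both factors changed. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets of a contrast, and an adjusted p under 0.05 was counted as a call. Changes between strata were compared by the interaction alone. Gene lists were tested with limma's camera at its preset correlation of 0.01, and once more with the correlation estimated from the data, on 1 probe set per gene. Of 30 lists fixed before the values were seen, 27 had at least 5 tested genes, and adjusted p-values ran over those lists within a contrast. Counts adjusted over the list alone apply the Benjamini-Hochberg method to its members only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

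Genes named in the text were chosen by a rule written before the values were seen. For the averaged contrasts these were up to 10 genes of largest change in each direction past the threshold with 1 sign in both strata, and for the other contrasts up to 5 in each direction. From each list with a call up to 4 members of smallest p were taken, from the other lists up to 2, and a short set of stress and lung genes was always eligible. The text names part of the genes so chosen. RT1-Bb was singled out after its values were seen, because its probe sets disagreed. A gene was represented by the brightest of its probe sets with a single symbol. The annotation of the array gave 1 symbol to 7006 probe sets, several to 308 and none to 1426, and 6985 symbols were matched by gene number to the current reference gene table. What a gene is known for was taken from general knowledge, not from the files.

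The procedure was tried on simulated data with the number of samples, filter and noise of the real arrays and 200 changed probe sets among 5244. Of changes of 1.5, 2 and 4 times, 37.3%, 83.6% and 95.5% were called for ventilation averaged over oxygen, 11.9%, 62.7% and 90.9% for ventilation at 21% oxygen, and 1.49%, 26.9% and 65.2% for the interaction. The limit that this trial had to pass for changes of 4 times was first set at 80% and was lowered to 60% after the interaction missed it. No call had the wrong sign, and between 1.78% and 6.55% of the calls were false. A list shifted by 1.5 times was called in each of the 4 simulated contrasts, and none of the 26 other lists was. The simulated noise was independent between probe sets, so the trial could not show false list calls that arise from correlated genes. The share of changed probe sets was also smaller than the 9.1% to 35.1% called in the real contrasts. The adjustment of p-values depends on that share, so the simulated rates need not hold there.

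Alternatives changed 1 choice at a time: quantile and cyclic loess normalization, offsets of 1% and 10%, no filter and a filter of 60%, other uses of the 2 arrays of the averaged sample, the letter or the lot line as a block, no trend, a looser threshold of 0.10, fits of only the groups compared, a fit of 1 factor, and each sample left out in turn. The lot line is the line for a lot batch in the description of 4 arrays, which gives no lot. For that block the 9 arrays were kept apart. Added after the values were seen were the brightest 10% of probe sets left out, fits within the arrays with or without the lot line, and each averaged contrast within a single level of the other factor.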

Results

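Gene expression was measured in rat lung with 9 oligonucleotide arrays. The lungs came from rats that breathed spontaneously or were mechanically ventilated, each with 21% or 100% oxygen, which gave a 2 by 2 layout of 4 groups. Each group held 2 samples, titled with the letters a and b, and the letter b sample of mechanical ventilation with 100% oxygen was measured on 2 arrays that were averaged and counted once, leaving 8 samples. Both titles of a group carry the number 1 before the letter, and no label says that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The deposited values are intensities on a linear scale with 2% trimmed means close to 801 on every array. Between 18.4% and 20.01% of the probe sets of an array were listed at or below 0. The brightest signals differed between groups: the 99th percentile lay between 7072 and 8357 on the 3 mechanical 100% arrays and between 9931 and 14581 on the other arrays. Precision is limited by the number of arrays. Levels are given as the mean intensity ± SD (n = 2 samples). Those of all 4 groups come in the order spontaneous 21%, spontaneous 100%, mechanical 21% and mechanical 100%. Parentheses after a gene hold its log2 change ± SE and adjusted p. Changes were taken on the log2(intensity + 40) scale, which understates those of low genes. Counts adjusted over the list alone are given with the higher genes first and the lower ones second.

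**Figure D1:**
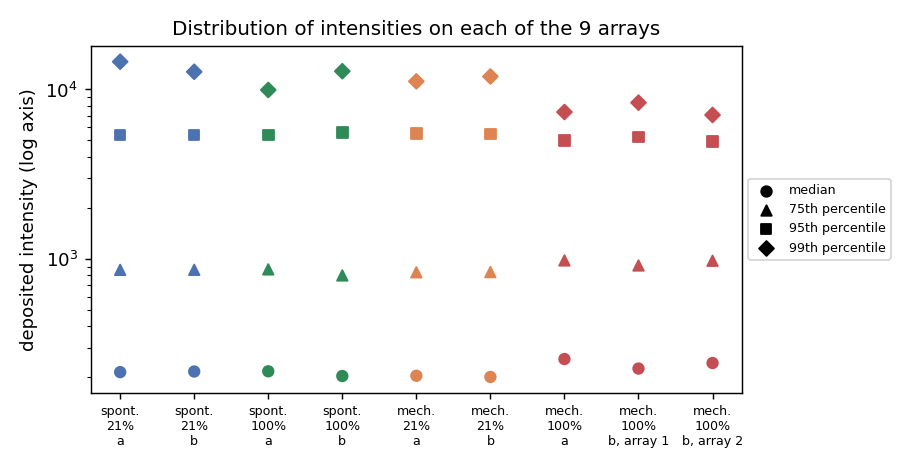
Median, 75th, 95th and 99th percentile of the deposited intensities (log axis) on each of the 9 arrays, coloured by group and labelled with the letter in the title. The medians of the arrays lie between 201 and 257, while the 99th percentiles of the mechanical 100% arrays, at most 8357, lie below those of all other arrays.

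The first comparison asked how mechanical ventilation differed from spontaneous breathing when both oxygen levels were averaged. Immediate early genes are transcription factors and regulators induced within minutes of a stimulus. Egr1, a zinc finger transcription factor, measured 1068 ± 99.5, 1666 ± 35.9, 1670.2 ± 128 and 6128 ± 418 in the 4 groups (1.24 ± 0.09, adjusted p = 2.6e-04). Nr4a1, an orphan nuclear receptor, rose on average (1.36 ± 0.17, adjusted p = 0.0040). So did the stress-induced factor Atf3 (0.99 ± 0.11, adjusted p = 0.0028), Myc (0.76 ± 0.12, adjusted p = 0.0095) and Fos (0.52 ± 0.09, adjusted p = 0.014). Of the 29 tested members of the immediate early list, 9 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.19 with an estimated correlation). At 21% oxygen alone the list was not called (median log2 change -0.14, camera adjusted p = 0.18). At 100% oxygen alone it was (median 0.83, camera adjusted p = 6.1e-06), though not with an estimated correlation. The difference between the oxygen levels is tested by the interaction below.

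Il6, the interleukin-6 gene, was listed at or below 0 in both spontaneous 21% samples and measured 473 ± 16.6, 381 ± 5.10 and 428 ± 4.87 in the spontaneous 100%, mechanical 21% and mechanical 100% groups. The monocyte attractant Ccl2 measured 365 ± 43.8, 1662 ± 209, 1425 ± 33.6 and 1394 ± 168 in the 4 groups (0.81 ± 0.11, adjusted p = 0.0054). The adhesion molecules Icam1 (0.55 ± 0.08, adjusted p = 0.0055) and Selp (0.62 ± 0.11, adjusted p = 0.018) rose, and the T cell attractant Ccl5 fell (-0.74 ± 0.11, adjusted p = 0.0073). In the cytokine and chemokine list 8 of 32 tested members rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.19 with an estimated correlation). Leaving out spontaneous 21% letter a, spontaneous 100% letter a or mechanical 100% letter a took this list to adjusted p = 0.070, 0.059 and 0.065. Among genes with the largest rise was RatNP-3b, a neutrophil defensin, at 18.8 ± 14.1, 60.2 ± 32.3, 1207 ± 127 and 279 ± 22.6 in the 4 groups (3.07 ± 0.21, adjusted p = 2.5e-04). Only its mechanical 21% mean lay above 302, the highest reading of a control probe set without a spiked target, so its change is rough. The neutrophil list was not called. Tff3, a mucosal trefoil peptide, rose (1.51 ± 0.18, adjusted p = 0.0033). Tissue factor F3 (0.66 ± 0.08, adjusted p = 0.0029) and the tissue plasminogen activator Plat (0.51 ± 0.09, adjusted p = 0.018) were higher too, as were the detoxification genes Cyp1a1 (1.04 ± 0.14, adjusted p = 0.0055) and Nqo1 (0.54 ± 0.09, adjusted p = 0.018). Several of these calls hung on single samples. Selp and Plat lost theirs without spontaneous 100% letter b, mechanical 21% letter a or mechanical 100% letter a. Plat and Fos did without mechanical 21% letter b, and Nqo1 without either mechanical 21% sample.

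In the fibroblast list 3 of 8 tested members fell and 0 rose (0 and 4 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.19 with an estimated correlation). The collagen gene Col1a2 was among those that fell (-0.57 ± 0.07, adjusted p = 0.0046). This list was no longer called after quantile normalization (adjusted p = 0.090). The surfactant protein genes Sftpb (-0.89 ± 0.17, adjusted p = 0.024) and Sftpc (-0.77 ± 0.17, adjusted p = 0.035) fell, while the alveolar type 2 list that holds them was not called (camera adjusted p = 0.094). The alveolar type 1 cell gene Ager (-0.56 ± 0.11, adjusted p = 0.024) and the haemoglobin gene Hbb (-1.14 ± 0.24, adjusted p = 0.028) fell too. These are among the brightest probe sets. After quantile normalization, which equalises the lower top of the mechanical 100% arrays, their log2 changes were -0.60, -0.59, -0.30 and -0.94, with Sftpb and Ager no longer past the threshold. All 4 genes also lost their call when either mechanical 21% sample, spontaneous 21% letter a, spontaneous 100% letter b or mechanical 100% letter a was left out. They lost it too without the filter on low signal, without the variance trend or with only the first array of the averaged sample. The inducible heat shock gene Hspa1a measured 6965 ± 41.6, 10788 ± 2641, 3965 ± 0.930 and 5885 ± 379 in the 4 groups (-0.83 ± 0.11, adjusted p = 0.0055).

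Markers of tissues other than lung parenchyma moved with the groups in this comparison. Of 13 tested skeletal muscle genes, 9 were lower with mechanical ventilation and 0 were higher (0 and 9 adjusted over the list alone, camera adjusted p = 1.5e-12, adjusted p = 0.036 with an estimated correlation). The fast troponin gene Tnnc2 measured 372 ± 60.1, 3869 ± 276, 502 ± 45.9 and 41.2 ± 24.6 in the 4 groups, and Myl11 fell with a log2 change of -2.49, adjusted p = 1.9e-04. The squamous keratin gene Krt4 measured 1177 ± 52.6 and 6557 ± 380.3 in the spontaneous groups and was listed at or below 0 in all mechanically ventilated samples. In the heart muscle list 5 of 12 tested members fell and 0 rose (0 and 5 adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.25 with an estimated correlation). Among T lymphocyte genes, the surface antigen gene Thy1 measured 212 ± 65.4, 183 ± 16.4, 8651 ± 1306 and 155 ± 24.4 in the 4 groups. For Cd3g the levels were 362 ± 2.12, 196 ± 51.6, 5055 ± 30.9 and 158 ± 31.4 in the 4 groups. Their list had 6 of 13 members higher and 1 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.0084, adjusted p = 0.19 with an estimated correlation). It was not called without the filter on low signal (adjusted p = 0.060).

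In all, 477 of the 5244 tested probe sets passed limma's moderated test at a Benjamini-Hochberg adjusted p under 0.05, 254 higher and 223 lower with mechanical ventilation. Quantile normalization gave 182 and 153, cyclic loess 224 and 184. A fit of ventilation alone, 4 samples against 4 without an oxygen term, called 5, Tff3 and Krt4 among them, and no other gene named above. The count was 222 without spontaneous 21% letter a, 147 without spontaneous 100% letter b, 148 without mechanical 21% letter a, 128 without mechanical 21% letter b, 204 without mechanical 100% letter a and 296 without mechanical 100% letter b. The range with any 1 sample left out was 128 to 518. Not all of the named changes passed at both oxygen levels, which by itself shows no difference between the levels. At 100% oxygen alone the log2 changes of Il6 -0.13, Ccl2 -0.25, Col1a2 0.09, Selp 0.36, Thy1 -0.20 and Cd3g -0.25 did not pass. At 21% oxygen alone those of Nr4a1 0.02, Myl11 -0.40, Hbb -0.73, Atf3 0.54, Myc 0.27, Icam1 -0.15, F3 0.08, Plat -0.03, Sftpb -0.41, Sftpc -0.56, Ager -0.38, Tnnc2 0.40 and Fos 0.02 did not pass.

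**Figure D2:**
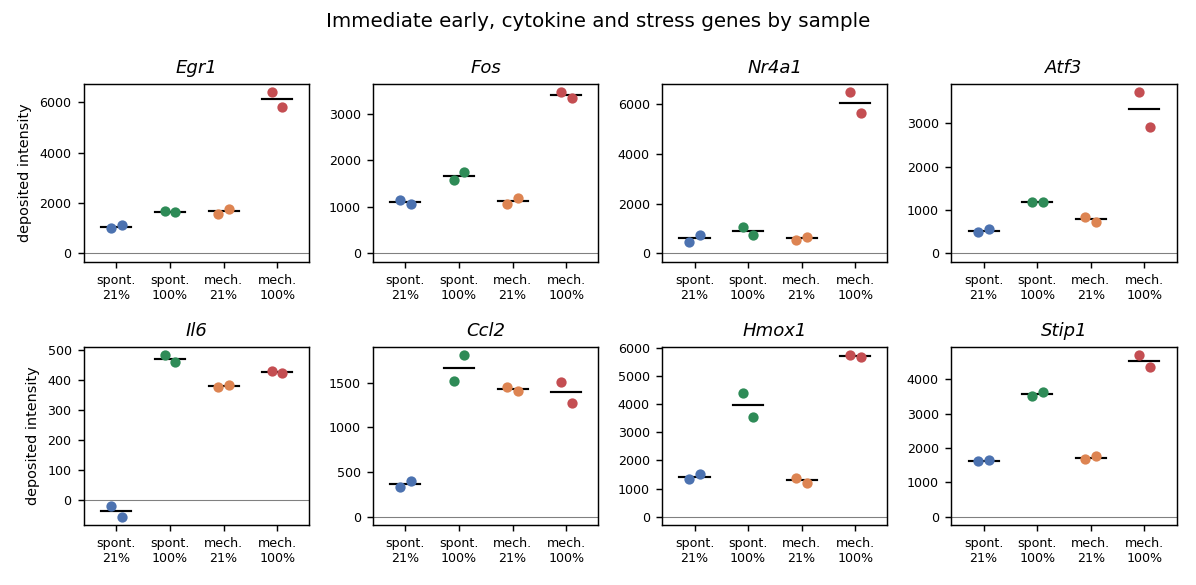
Deposited intensity (linear axis) of 8 immediate early, cytokine and stress genes in each of the 8 samples, by group; points are samples and the line is the mean of the 2 samples. Egr1 reaches 6128 in the mechanical 100% group against 1068 in the spontaneous 21% group, and Hmox1 is higher at 100% than at 21% oxygen under both ways of breathing.

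The second comparison set 100% against 21% oxygen, averaged over the way of breathing. Hmox1, haem oxygenase 1, is an enzyme that breaks down haem and is induced by oxidants. It measured 1424 ± 131, 3973 ± 592, 1290.5 ± 129.8 and 5723 ± 45.3 in the 4 groups (1.78 ± 0.10, adjusted p = 4.0e-05). Thioredoxin reductase Txnrd1 rose as well (0.74 ± 0.14, adjusted p = 0.0093). The aryl hydrocarbon receptor target Cyp1a1 fell (-1.76 ± 0.14, adjusted p = 2.2e-04), and so did Gpx3, a secreted glutathione peroxidase (-0.60 ± 0.12, adjusted p = 0.011). In the heat shock list 12 of 25 tested members rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.0010, adjusted p = 0.32 with an estimated correlation). The Hsp90 co-chaperone Stip1 measured 1638 ± 15.8, 3571 ± 76.6, 1723 ± 57.9 and 4542 ± 245 in the 4 groups (1.24 ± 0.08, adjusted p = 6.6e-05). Fkbp4 (1.41 ± 0.10, adjusted p = 1.4e-04), the mitochondrial chaperonin Hspd1 (0.93 ± 0.09, adjusted p = 4.1e-04) and Dnajb1 (0.88 ± 0.08, adjusted p = 5.5e-04) rose. Without the filter on low signal Txnrd1 and Gpx3 were not called.

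Of 29 immediate early genes, 13 rose with oxygen and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 7.7e-04, adjusted p = 0.18 with an estimated correlation). Among those that rose were Atf3 (1.57 ± 0.11, adjusted p = 1.4e-04), Egr1 (1.24 ± 0.09, adjusted p = 1.4e-04), the mRNA decay factor Zfp36 (1.18 ± 0.09, adjusted p = 1.7e-04) and Fos (1.07 ± 0.09, adjusted p = 2.2e-04). Crem, a cyclic AMP responsive regulator, measured 311 ± 11.5, 1549 ± 71.6, 1022 ± 22.4 and 2442 ± 128 in the 4 groups (1.70 ± 0.09, adjusted p = 2.8e-05). Ccl2 was higher with a log2 change of 1.02, adjusted p = 9.8e-04, as were the chemokine gene Ccl3 (1.65 ± 0.31, adjusted p = 0.0092) and Socs3, an inhibitor of cytokine signalling (1.73 ± 0.43, adjusted p = 0.023). The Socs3 call was lost without spontaneous 21% letter b, spontaneous 100% letter a or mechanical 100% letter a, and both Ccl3 and Socs3 were lost without the filter. P4ha1, a collagen prolyl hydroxylase, rose (0.74 ± 0.07, adjusted p = 5.5e-04). The membrane carbonic anhydrase Car4 fell (-1.24 ± 0.09, adjusted p = 1.2e-04). Rup2, a gene without an assigned function here, measured 16.1 ± 17.9, 602 ± 97.9, 217 ± 11.6 and 535 ± 5.64 in the 4 groups. Levels of Ttr, the thyroid hormone carrier, were 85.7 ± 37.6, 793 ± 152, 461 ± 44.0 and 798 ± 19.6 in the 4 groups.

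In the cell cycle list 6 of 17 genes fell with oxygen and 1 rose (1 and 7 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.37 with an estimated correlation). Top2a (-0.57 ± 0.13, adjusted p = 0.016) and Cdk1 (-0.49 ± 0.11, adjusted p = 0.019) are examples. Over spontaneous 21%, the sample medians of the list were 0.45 and 0.31 in mechanical 21%. They were 0.068 and 0.0079 in spontaneous 100% and 0.063 and -0.072 in mechanical 100%. The lower average thus came mainly from high levels in mechanical 21%, the group with the highest Cd3g and Ucp1 (below). A link between them was not tested. Top2a lost its call without spontaneous 100% letter a, mechanical 21% letter a or the filter, and Cdk1 without mechanical 21% letter b or mechanical 100% letter a. Without spontaneous 21% letter b, spontaneous 100% letter a, mechanical 21% letter a or mechanical 100% letter b this list had adjusted p = 0.11, 0.052, 0.085 and 0.056. The interferon induced list had 7 of 17 members lower and 2 higher (2 and 8 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.18 with an estimated correlation). The cytoskeleton and adhesion list had 11 of 26 lower and 2 higher (2 and 13, camera adjusted p = 0.0015, adjusted p = 0.18 with an estimated correlation). Both were lost under quantile normalization (adjusted p = 0.12 and 0.14), the second also under cyclic loess (adjusted p = 0.067). The antigen transporter Tap2 fell (-0.74 ± 0.10, adjusted p = 0.0031), as did the keratin Krt19 (-0.54 ± 0.08, adjusted p = 0.0043). The T and natural killer lymphocyte list had 8 of 13 members lower and 1 higher (1 and 9 adjusted over the list alone, camera adjusted p = 5.0e-06, adjusted p = 0.14 with an estimated correlation). The fat list had 4 of 6 lower and 0 higher (0 and 5, camera adjusted p = 4.3e-04, adjusted p = 0.18 with an estimated correlation). In the mechanical 21% group Cd3g stood at 5055 ± 30.9 against at most 362 ± 2.12 elsewhere. The brown fat uncoupling protein Ucp1 stood there at 6213 ± 48.3 against at most 1093 ± 7.99.

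With oxygen, 1310 probe sets changed, 669 higher and 641 lower. The balance turned to 546 and 698 under quantile normalization and 575 and 678 under cyclic loess. The fit of oxygen alone, 4 samples against 4, called 63, among them Hmox1, Stip1, Fkbp4, Hspd1, Dnajb1, Car4 and P4ha1 and no other gene named above. The count was 639 without mechanical 21% letter b and 726 without mechanical 100% letter a. Over all samples left out in turn it lay between 639 and 1126. In the mechanically ventilated rats alone the log2 changes of Ccl2 -0.04 and Krt19 -0.12 did not pass. In the spontaneously breathing rats alone those of Socs3 0.96, Ccl3 0.96, Zfp36 0.40, Txnrd1 0.62, Gpx3 -0.41, Top2a -0.42 and Cdk1 -0.20 did not. Ucp1, lower with oxygen on average, rose in the latter (1.92).

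At 21% oxygen alone, mechanical ventilation was set against spontaneous breathing to see its effect without added oxygen. Among inflammatory signals, Ccl2 rose (1.86 ± 0.16, adjusted p = 4.3e-04), Selp rose (0.88 ± 0.15, adjusted p = 0.010), and Il6 went from at or below 0 to 381 ± 5.10. Egr1 rose (0.63 ± 0.13, adjusted p = 0.016), whereas Fos did not pass (0.02 ± 0.12, adjusted p = 0.93). The early factors Klf4 (-0.94 ± 0.13, adjusted p = 0.0046) and Zfp36 (-0.66 ± 0.13, adjusted p = 0.015) fell. The Egr1 call was lost without spontaneous 21% letter a, without mechanical 21% letter b and in the fit of only the groups compared. Zfp36 lost its call without spontaneous 21% letter b or either mechanical 21% sample, and Selp without mechanical 21% letter a. Of 27 oxidative phosphorylation genes, 13 rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 9.0e-08, adjusted p = 0.24 with an estimated correlation). Those that rose included the complex III subunit Uqcrfs1 (0.83 ± 0.13, adjusted p = 0.0070) and the ATP synthase subunit Atp5f1c (0.75 ± 0.13, adjusted p = 0.0098), whose call was lost without mechanical 21% letter b. Of 32 extracellular matrix genes, 14 fell and 0 rose (0 and 15 adjusted over the list alone, camera adjusted p = 6.6e-04, adjusted p = 0.24 with an estimated correlation). Fibronectin Fn1 went from 6894 ± 685 to 2508 ± 31.4 (-1.44 ± 0.12, adjusted p = 4.3e-04). Laminin Lamb2 fell (-1.76 ± 0.14, adjusted p = 3.2e-04), and so did Col1a2 (-1.23 ± 0.11, adjusted p = 4.4e-04). In the fibroblast list 4 of 8 fell and 0 rose (0 and 4, camera adjusted p = 0.0080, adjusted p = 0.24 with an estimated correlation).

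Among T lymphocyte genes, strong rises were those of Thy1 (5.13 ± 0.22, adjusted p = 1.2e-05), the T cell receptor complex gene Cd3d (4.01 ± 0.42, adjusted p = 0.0012) and the kinase Lck (3.06 ± 0.23, adjusted p = 3.2e-04). Of the 13 tested T and natural killer genes, 8 rose and 1 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.24 with an estimated correlation). Ucp1 rose from 259.6 ± 16.4 to 6213 ± 48.3 (4.38 ± 0.15, adjusted p = 6.7e-06), and Fabp4, a fatty acid binding protein gene, from 501 ± 58.8 to 3422 ± 49.2 (2.68 ± 0.22, adjusted p = 3.8e-04). The fat list that holds them was not called, with 3 of 6 higher and 1 lower (3 and 1, camera adjusted p = 0.078). The desaturase gene Scd, of the alveolar type 2 list, rose from 1218 ± 75.1 to 6608 ± 52.5 (2.40 ± 0.11, adjusted p = 1.2e-05). That list as a whole did not rise with it, with sample medians of -0.29 and -0.25 in mechanical 21% over spontaneous 21%. In the cell cycle list 7 of 17 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.0029, adjusted p = 0.29 with an estimated correlation), with Ccnb1 (1.47 ± 0.24, adjusted p = 0.0075) and Pcna (0.63 ± 0.12, adjusted p = 0.012) higher. Neither gene was called when either mechanical 21% sample was left out. The list call was lost without spontaneous 21% letter a (adjusted p = 0.065). The heart muscle list had 2 of 12 higher and 0 lower (4 and 0, camera adjusted p = 0.013, adjusted p = 0.29 with an estimated correlation). It lost its call without mechanical 21% letter b (adjusted p = 0.099). In total 760 probe sets changed, 367 higher and 393 lower, against 374 and 386 under quantile normalization and 444 and 377 under cyclic loess. The count was 393 without spontaneous 21% letter b, 304 without mechanical 21% letter a and 216 without mechanical 21% letter b. The range with any 1 sample left out was 216 to 701. Only the spontaneous 21% samples of this pair carry a line for a lot batch in their description. The fit with that line as a block keeps the 2 arrays of the averaged sample apart. It called 106 probe sets here, against 895 with the arrays apart and no block. Under that block, which widens the error of this contrast, Egr1, Selp, Uqcrfs1, Atp5f1c, Ccnb1, Pcna, Cd3d, Klf4 and Zfp36 no longer passed, with log2 changes of 0.74, 0.95, 0.71, 0.74, 1.42, 0.65, 3.17, -1.01 and -0.64.

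At 100% oxygen, 18 of 29 immediate early genes rose with mechanical ventilation and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 6.1e-06, adjusted p = 0.15 with an estimated correlation). Nr4a1 rose from 914 ± 223 to 6070.4 ± 615 (2.70 ± 0.24, adjusted p = 5.0e-04), and Fos from 1669 ± 119 to 3407 ± 103 (1.01 ± 0.12, adjusted p = 0.0020). Egr1 (1.85 ± 0.13, adjusted p = 8.6e-05) and Atf3 (1.44 ± 0.16, adjusted p = 0.0014) rose with them. Icam1 (1.25 ± 0.11, adjusted p = 4.5e-04), the chemokine Cx3cl1 (1.18 ± 0.15, adjusted p = 0.0023) and the NF-kappa-B inhibitor Nfkbia (0.94 ± 0.12, adjusted p = 0.0024) rose too. Il6 did not pass (473 ± 16.6 against 428 ± 4.87). Of 32 matrix genes, 15 rose and 1 fell (15 and 1, camera adjusted p = 0.0058, adjusted p = 0.26 with an estimated correlation). Risers were Fn1 (0.98 ± 0.12, adjusted p = 0.0020), lysyl oxidase Lox (1.07 ± 0.11, adjusted p = 7.9e-04) and elastin Eln (0.84 ± 0.10, adjusted p = 0.0020). Of 10 endothelial genes, 5 rose and 0 fell (6 and 0, camera adjusted p = 0.0058, adjusted p = 0.15 with an estimated correlation). Ace, the angiotensin converting enzyme gene, went from 2298 ± 243 to 4775 ± 29.0 (1.05 ± 0.11, adjusted p = 0.0013).

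Of 27 oxidative phosphorylation genes, 17 fell at 100% oxygen and 0 rose (0 and 18 adjusted over the list alone, camera adjusted p = 2.6e-10, adjusted p = 0.15 with an estimated correlation). The cytochrome oxidase subunit genes Cox6a2 (-1.13 ± 0.15, adjusted p = 0.0029), Cox4i1 (-0.94 ± 0.18, adjusted p = 0.0092) and Cox8a (-0.95 ± 0.18, adjusted p = 0.0093) were examples. Cox6a2 is a heart and skeletal muscle form, and the other pair are bright probe sets. Of 13 skeletal muscle genes, 10 fell and 0 rose (0 and 11, camera adjusted p = 2.8e-13, adjusted p = 0.032 with an estimated correlation). Tnnc2 went from 3869 ± 276 to 41.2 ± 24.6 (-5.62 ± 0.24, adjusted p = 5.3e-06). The muscle creatine kinase Ckm fell from 4858 ± 111 to 504 ± 40.4 (-3.17 ± 0.16, adjusted p = 1.6e-05). In the heart muscle list 7 of 12 fell and 0 rose (0 and 8, camera adjusted p = 1.4e-06, adjusted p = 0.15 with an estimated correlation). Of 1413 probe sets called, 868 were higher and 545 lower. Much of that imbalance went with the scaling, as quantile normalization gave 602 and 519 and cyclic loess 551 and 469. The count was 464 without spontaneous 100% letter b, 513 without mechanical 100% letter a and 882 without mechanical 100% letter b. Over all samples left out in turn it lay between 464 and 1423. The median change of all tested probe sets was 0.13 and moved to -0.01 under quantile normalization. With the lot line as a block 470 probe sets were called, against 1704 with the arrays apart and no block. Cox4i1 and Cox8a did not pass under that block (log2 changes -0.60 and -0.64), nor without the filter or without mechanical 100% letter a. The arrays without the line include a single mechanical 100% array. A fit within them gave these genes the same changes as the block, so it is not a separate check.

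In spontaneously breathing rats, oxygen was compared without the ventilator. Hmox1 rose from 1424 ± 131 to 3973 ± 592 (1.45 ± 0.14, adjusted p = 7.7e-04). Stip1 (1.11 ± 0.11, adjusted p = 7.1e-04) and Fkbp4 (1.23 ± 0.14, adjusted p = 0.0017) rose, with 9 of 25 heat shock genes higher and 0 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.0021, adjusted p = 0.43 with an estimated correlation). That list was not called without spontaneous 100% letter b (adjusted p = 0.062). Ccl2 rose from 365 ± 43.8 to 1662 ± 209 (2.07 ± 0.16, adjusted p = 2.6e-04) and Atf3 rose (1.11 ± 0.16, adjusted p = 0.0044). In contrast Icam1 (-0.77 ± 0.11, adjusted p = 0.0040), Nfkbia (-0.88 ± 0.12, adjusted p = 0.0036) and Klf4 (-1.67 ± 0.13, adjusted p = 3.1e-04) fell. Car4, a lung endothelial carbonic anhydrase, fell from 2642 ± 4.48 to 846 ± 16.7 (-1.60 ± 0.12, adjusted p = 2.6e-04). Ace fell from 5364 ± 209.9 to 2298 ± 243 (-1.21 ± 0.11, adjusted p = 6.7e-04). Endothelial genes had 5 of 10 lower and 0 higher (1 and 5 adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.26 with an estimated correlation). This call was lost without spontaneous 21% letter b or spontaneous 100% letter a (adjusted p = 0.072 and 0.051). Matrix genes had 9 of 32 lower and 0 higher (0 and 11, camera adjusted p = 0.0010, adjusted p = 0.26 with an estimated correlation). Cytoskeleton and adhesion genes had 9 of 26 lower and 0 higher (1 and 14, camera adjusted p = 8.9e-04, adjusted p = 0.22 with an estimated correlation). Oxidative phosphorylation genes had 10 of 27 higher and 0 lower (13 and 0, camera adjusted p = 2.2e-05, adjusted p = 0.30 with an estimated correlation).

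In this comparison the skeletal muscle list had 10 of 13 members higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 1.8e-10, adjusted p = 0.051 with an estimated correlation). Skeletal actin Acta1 rose from 1898 ± 133 to 7119 ± 574 (1.88 ± 0.13, adjusted p = 2.1e-04). Ckm rose from 942 ± 157 to 4858 ± 111 (2.33 ± 0.16, adjusted p = 2.1e-04) and Tnni2 from 97.4 ± 27.0 to 1444 ± 65.8 (3.45 ± 0.26, adjusted p = 2.6e-04). Heart muscle had 6 of 12 higher and 0 lower (6 and 0, camera adjusted p = 8.7e-06, adjusted p = 0.22 with an estimated correlation). The atrial light chain Myl7 was among them (1.12 ± 0.12, adjusted p = 0.0014). In this pair 879 probe sets changed, 370 higher and 509 lower, with 393 and 503 under quantile normalization and 470 and 505 under cyclic loess. The count was 438 without spontaneous 21% letter a, 560 without spontaneous 21% letter b, 395 without spontaneous 100% letter a and 364 without spontaneous 100% letter b. The range with any 1 sample left out was 364 to 794. Both spontaneous 21% arrays and neither spontaneous 100% array carry the lot line. With it as a block 121 probe sets were called, against 1029 with the arrays apart and no block, with Icam1 no longer past the threshold (log2 change -0.58).

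In mechanically ventilated rats, 17 of 29 immediate early genes rose with oxygen and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 3.0e-06, adjusted p = 0.12 with an estimated correlation). Nr4a3 rose from 86.5 ± 13 to 1249 ± 501 (3.30 ± 0.33, adjusted p = 4.6e-04) and Nr4a1 from 604 ± 63.4 to 6070.4 ± 615 (3.25 ± 0.24, adjusted p = 1.1e-04). Zfp36 rose from 1107 ± 58.0 to 4413 ± 20.1 (1.96 ± 0.13, adjusted p = 7.6e-05) and Fos from 1127 ± 88.7 to 3407 ± 103 (1.56 ± 0.12, adjusted p = 1.5e-04). Hmox1 rose from 1290.5 ± 129.8 to 5723 ± 45.3 (2.12 ± 0.14, adjusted p = 8.0e-05). Il1a, the interleukin-1 alpha gene, was higher (1.11 ± 0.14, adjusted p = 0.0011). The heat shock list had 12 of 25 higher and 2 lower (12 and 2, camera adjusted p = 0.030, adjusted p = 0.41 with an estimated correlation). Without mechanical 100% letter b it was not called (adjusted p = 0.082). Matrix genes had 14 of 32 higher and 2 lower (15 and 3, camera adjusted p = 0.0034, adjusted p = 0.20 with an estimated correlation). Fn1 measured 2508 ± 31.4 and 7683 ± 607 (1.60 ± 0.12, adjusted p = 1.2e-04).

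Under ventilation 18 of 27 oxidative phosphorylation genes fell with oxygen and 0 rose (0 and 19 adjusted over the list alone, camera adjusted p = 7.9e-09, adjusted p = 0.19 with an estimated correlation). One that fell was the ATP synthase subunit Atp5po (-1.16 ± 0.15, adjusted p = 0.0014). Cell cycle genes had 7 of 17 lower and 2 higher (2 and 7, camera adjusted p = 0.0052, adjusted p = 0.30 with an estimated correlation). T and natural killer genes had 8 of 13 lower and 1 higher (1 and 8, camera adjusted p = 4.6e-06, adjusted p = 0.084 with an estimated correlation). Fat genes had 3 of 6 lower and 0 higher (0 and 3, camera adjusted p = 0.0052, adjusted p = 0.20 with an estimated correlation). For skeletal muscle it was 9 of 13 lower and 0 higher (0 and 9, camera adjusted p = 4.6e-06, adjusted p = 0.084 with an estimated correlation), and for heart muscle 6 of 12 lower and 1 higher (1 and 7, camera adjusted p = 0.0052, adjusted p = 0.25 with an estimated correlation). Ucp1 fell from 6213 ± 48.3 to 34.5 ± 4.79 (-6.39 ± 0.15, adjusted p = 1.6e-07) and Fabp4 from 3422 ± 49.2 to 55.4 ± 31.3 (-5.26 ± 0.22, adjusted p = 5.0e-06). Without the filter on low signal the fat list was not called (adjusted p = 0.13). The antioxidant list had 11 of 33 lower and 5 higher (5 and 12, camera adjusted p = 0.035, adjusted p = 0.32 with an estimated correlation). The interferon list had 9 of 17 lower and 3 higher (3 and 9, camera adjusted p = 0.026, adjusted p = 0.20 with an estimated correlation). Both lost their calls under quantile normalization (adjusted p = 0.20 and 0.20), under cyclic loess (adjusted p = 0.27 and 0.071), without the filter (adjusted p = 0.075 and 0.051) and without mechanical 100% letter b (adjusted p = 0.055 and 0.065). The antioxidant list also lost it without mechanical 21% letter a or mechanical 100% letter a (adjusted p = 0.068 and 0.085).

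This pair had 1841 probe sets called, 1085 higher and 756 lower. Under quantile normalization 816 were higher and 861 lower, and under cyclic loess 773 and 823. The former moved the median change of all probe sets from 0.14 to 0.01. The count was 1140 without mechanical 21% letter a, 956 without mechanical 21% letter b and 977 without mechanical 100% letter a. Over all samples left out in turn it lay between 956 and 1899. With the lot line as a block 898 were called, against 2138 with the arrays apart and no block.

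The interaction asked whether ventilation changed genes differently at 100% than at 21% oxygen, with positive values for a larger rise at 100%. Of 29 immediate early genes, 17 had positive interactions and 0 negative ones (19 and 0 adjusted over the list alone, camera adjusted p = 3.4e-05, adjusted p = 0.13 with an estimated correlation). Values were positive for Nr4a1 (2.67 ± 0.34, adjusted p = 0.0014), Egr1 (1.23 ± 0.18, adjusted p = 0.0024) and Fos (0.99 ± 0.18, adjusted p = 0.0051). Matrix genes were positive in 13 of 32 and negative in 0 (16 and 1, camera adjusted p = 1.7e-04, adjusted p = 0.13 with an estimated correlation). Fn1 measured 6894 ± 685, 3861 ± 226, 2508 ± 31.4 and 7683 ± 607 in the 4 groups (2.43 ± 0.17, adjusted p = 1.2e-04). Endothelial genes were positive in 7 of 10 and negative in 0 (8 and 0, camera adjusted p = 0.019, adjusted p = 0.16 with an estimated correlation), for instance Ace (2.20 ± 0.16, adjusted p = 1.3e-04). The spectrin gene Sptan1 (4.08 ± 0.24, adjusted p = 4.9e-05) and the guidance factor Slit3 (3.87 ± 0.34, adjusted p = 2.6e-04) were among the largest positive values. Oxidative phosphorylation genes were negative in 21 of 27 and positive in 0 (0 and 24 adjusted over the list alone, camera adjusted p = 5.6e-12, adjusted p = 0.13 with an estimated correlation). Uqcrfs1 is an example (-1.48 ± 0.19, adjusted p = 0.0014).

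Some muscle, lymphocyte and fat genes were among the largest negative interactions. They include Ucp1 (-8.31 ± 0.21, adjusted p = 3.1e-07), Fabp4 (-6.53 ± 0.31, adjusted p = 1.6e-05), Tnnc2 (-6.02 ± 0.33, adjusted p = 4.2e-05) and Thy1 (-5.32 ± 0.32, adjusted p = 4.9e-05). Each of them had a group mean under 302, the highest reading of a control probe set without a spiked target, so these sizes are rough. Skeletal muscle genes were negative in 10 of 13 and positive in 0 (0 and 10 adjusted over the list alone, camera adjusted p = 3.1e-10, adjusted p = 0.056 with an estimated correlation). Heart muscle genes were negative in 8 of 12 and positive in 0 (0 and 9, camera adjusted p = 5.3e-06, adjusted p = 0.13 with an estimated correlation). T and natural killer genes were negative in 7 of 13 and positive in 2 (2 and 8, camera adjusted p = 0.0011, adjusted p = 0.13 with an estimated correlation). The cell cycle list was negative in 4 of 17 and positive in 2 (2 and 4, camera adjusted p = 0.021, adjusted p = 0.46 with an estimated correlation). It lost its call without spontaneous 21% letter a or mechanical 21% letter a (adjusted p = 0.099 and 0.052). Across all tested probe sets, which are not independent replicates, the ventilation changes at 21% and at 100% oxygen, which share no array, had a Pearson r of -0.27 and a Spearman rho of -0.30. Of 357 probe sets called at both oxygen levels, 49 changed in one direction and 308 in opposite directions.

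The interaction test called 1439 probe sets, 888 positive and 551 negative, and between 980 and 1318 with 1 sample left out. Quantile normalization gave 714 positive and 679 negative, and cyclic loess 657 and 682. The median interaction of all probe sets moved from 0.15 to 0.00 under the former. The lot line stands on both spontaneous 21% arrays and on 2 of the 3 mechanical 100% arrays and on no array of the other groups, so it runs along the interaction. With it as a block 151 probe sets were called, against 1631 with the arrays apart and no block. Nr4a1, Egr1, Fos and Uqcrfs1 did not pass under that block, with interactions of 2.55, 1.02, 0.93 and -1.24 and wider errors.

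**Figure D3:**
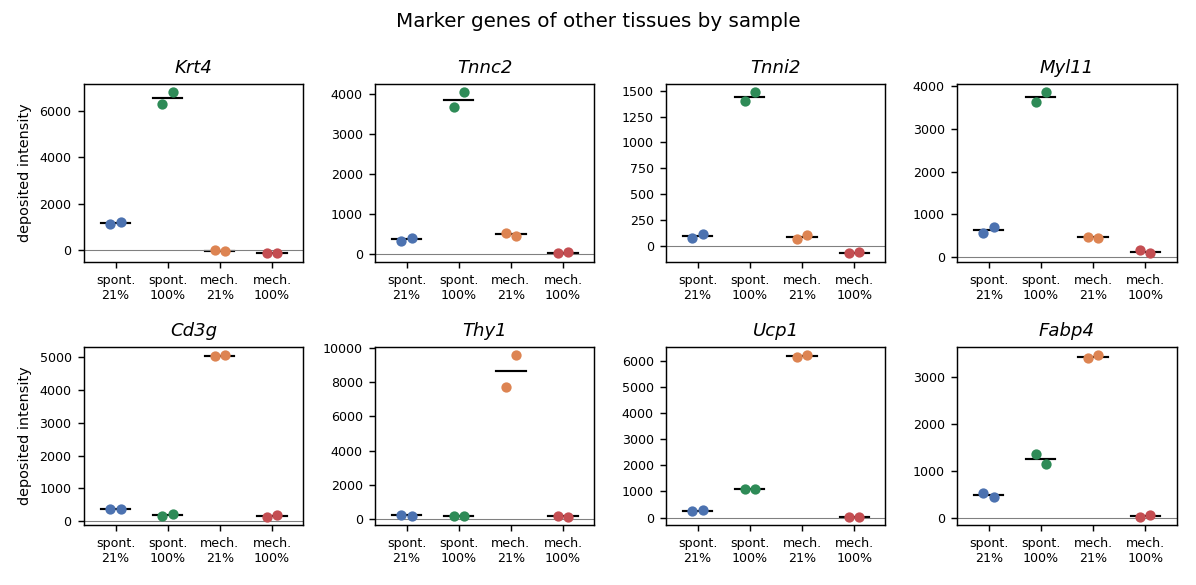
Deposited intensity (linear axis) of 8 marker genes of squamous epithelium, striated muscle, T lymphocytes and fat in each of the 8 samples, by group; points are samples and the line is the mean of the 2 samples. The striated muscle genes peak in the spontaneous 100% group (Tnnc2 at 3869), and Thy1 (8651), Cd3g, Ucp1 and Fabp4 in the mechanical 21% group, with both samples of a group close together.

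Mechanical ventilation with 100% oxygen was last set against spontaneous breathing of 21% oxygen, the pair in which both factors changed and most arrays carry the lot line. Of 29 immediate early genes, 12 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 3.5e-05, adjusted p = 0.13 with an estimated correlation). Nr4a1 rose from 608 ± 201 to 6070.4 ± 615 (3.27 ± 0.24, adjusted p = 1.9e-04) and Atf3 from 526 ± 56.1 to 3316 ± 578 (2.56 ± 0.16, adjusted p = 1.1e-04). Egr1 (2.48 ± 0.13, adjusted p = 3.8e-05) and Fos (1.58 ± 0.12, adjusted p = 2.4e-04) were higher. Crem went from 311 ± 11.5 to 2442 ± 128 (2.82 ± 0.12, adjusted p = 2.1e-05). Of 32 cytokine genes, 8 rose and 1 fell (13 and 2, camera adjusted p = 0.0028, adjusted p = 0.13 with an estimated correlation), with Ccl2 among the former (1.82 ± 0.16, adjusted p = 4.1e-04). Il6 was listed at or below 0 in the spontaneous 21% group and measured 428 ± 4.87 in the other. Hmox1 rose from 1424 ± 131 to 5723 ± 45.3 (1.98 ± 0.14, adjusted p = 1.9e-04). The growth arrest and p53 list had 4 of 10 higher and 0 lower (4 and 0, camera adjusted p = 0.024, adjusted p = 0.30 with an estimated correlation). The heat shock list had 9 of 25 higher and 3 lower (9 and 4, camera adjusted p = 0.042, adjusted p = 0.45 with an estimated correlation).

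Of 13 skeletal muscle genes, 6 were lower in the mechanical 100% group and 0 higher (0 and 8 adjusted over the list alone, camera adjusted p = 3.7e-06, adjusted p = 0.13 with an estimated correlation). Fat genes were lower in 2 of 6 and higher in 0 (0 and 3, camera adjusted p = 6.9e-04, adjusted p = 0.13 with an estimated correlation). T and natural killer genes were lower in 2 of 13 and higher in 0 (1 and 4, camera adjusted p = 0.013, adjusted p = 0.18 with an estimated correlation). Sftpc fell from 12722 ± 2963 to 3902 ± 508 (-1.69 ± 0.24, adjusted p = 0.0041), with a log2 change of -1.36 under quantile normalization and no call without the filter. The alveolar type 2 list had 3 of 7 lower and 0 higher (0 and 3, camera adjusted p = 0.040, adjusted p = 0.28 with an estimated correlation). Cytoskeleton and adhesion genes had 9 of 26 lower and 0 higher (1 and 9, camera adjusted p = 0.014, adjusted p = 0.19 with an estimated correlation). Oxidative phosphorylation genes had 5 of 27 lower and 0 higher (0 and 5, camera adjusted p = 0.040, adjusted p = 0.45 with an estimated correlation). The last 3 lists were not called under quantile normalization (adjusted p = 0.97, 0.97 and 0.11) or cyclic loess (adjusted p = 0.65, 0.52 and 0.91). The growth arrest list was not called under quantile normalization (adjusted p = 0.053), without spontaneous 21% letter a (adjusted p = 0.11) or without mechanical 100% letter a (adjusted p = 0.061). Without spontaneous 21% letter b or mechanical 100% letter a the calls of the alveolar type 2 list (adjusted p = 0.075 and 0.075) and the oxidative phosphorylation list (adjusted p = 0.16 and 0.33) were lost. So were they without the filter (adjusted p = 0.14 and 0.058). The heat shock call was lost on leaving out any spontaneous sample or mechanical 100% letter b, with adjusted p up to 0.12. Here 761 probe sets changed, 393 higher and 368 lower, which became 321 and 349 under quantile normalization and 307 and 352 under cyclic loess. The count was 449 without spontaneous 21% letter a and 314 without mechanical 100% letter a. Over all samples left out in turn it lay between 314 and 674. Within the arrays that carry the lot line 585 were called. The median change of all tested probe sets was 0.10 and -0.01 under quantile normalization.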

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

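The tests of compression, of the lot line, of tissue from beside the lung and of a single RNA source were chosen after the results were seen, while the interaction test, quantile normalization and the splits of the samples were planned. The results below were picked out because the change with ventilation differed between 21% and 100% oxygen. The interaction test called 1439 probe sets. Among named genes, interactions in log2 were positive for Trappc10 3.10, Nr4a1 2.67, Nr4a3 2.63, Egr1 1.23 and Hmox1 0.67. Negative values were found for the T cell genes Thy1 -5.32, Cd8a -5.07, Cd3d -4.34, Cd3g -3.92, Cd247 -2.68 and Cd8b -1.79, with Septin1 -2.54, and for the muscle gene Myl11 -4.18. H19 -2.96, Rup2 -2.38, Fut1 -2.34, Ttr -2.01, Ndufaf3 -1.63, Car3 -1.46 and Crem -0.96 were negative too, as was the defensin RatNP-3b -2.72. For Plscr3 3.43, Tnni2 -5.08, Or2t26 -3.45 and Il6 -3.53 one group was listed at or below 0, so the size of the value is set in part by that floor. Krt4 -2.44 was at or below 0 in both mechanical groups, so its value is only the oxygen change of the spontaneous groups with its sign turned, and says nothing on the response to ventilation. Of the genes listed, only Nr4a1, Cd8b, Egr1, Ndufaf3, Hmox1 and Crem had all 4 group means above 302, the highest reading of a control probe set without a spiked target, so the size of the other values is rough.

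Changes with ventilation often ran in opposite directions at the 2 oxygen levels. Compression of bright signals on the mechanical 100% arrays is argued against as the whole cause. Under quantile normalization 81.4% of the calls (1171 of 1439) kept their sign and call. For ventilation at 100% oxygen the median change of the oxidative phosphorylation genes was -0.61. It lay at percentile 0 of 10000 lists of equal brightness (95% between -0.30 and 0.12). That list had already been called lower in the same contrast when the test was chosen, so its percentile adds no separate support. Tissue from beside the lung was not tested for this list and stays open: over spontaneous 21%, the sample medians were 0.46 and 0.49, 0.56 and 0.49, -0.11 and -0.0024 for it, 1.01 and 0.71, 0.45 and 0.48, -0.015 and -0.092 for heart muscle and 0.52 and 0.60, 0.81 and 1.09, -0.98 and -0.35 for fat in spontaneous 100%, mechanical 21% and mechanical 100%, in turn. The lot line runs along the interaction, and only 1 sample lies on both sides of it. From the difference between its 2 arrays a median share of 0.051 of each called interaction was predicted, with the predicted sign in 60.6% of calls. The 95% bootstrap interval, 0.042 to 0.061, came from resampled probe sets and does not measure how a lot effect varies between samples. A single sample on both sides excludes nothing, since a batch of animals or of RNA would not show between 2 arrays of one RNA, so the interaction and the lot cannot be told apart. A real dependence of the response on oxygen stays open and untested.

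Markers of other tissues stood far apart between groups. Scaling or compression is argued against for the muscle genes, whose median rise in spontaneous 100% was 1.75 under quantile normalization. Tissue from beside the lung in the RNA may account for the muscle genes, of which 10 of 13 rose in spontaneous 100% and 0 fell, and T cells or tissue rich in them for 8 of 13 T and natural killer genes that rose in mechanical 21%, with 1 lower. The criterion for these counts was changed more than once after values were seen, from a few T cell genes picked by hand, to the whole list with no member allowed to fall, to most of the list higher, and under the stricter middle version the T cell test would not have been met. For fat the count was 3 of 6 higher and 1 lower, so fat beside the lung stays open, as does an influx of lymphocytes into the lung.

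The letter a and b samples of a group carried nearly the same levels of these markers, so RNA of a single source was asked about. The median difference between letters a and b over the 32 muscle, T cell and fat genes was 0.21 log2, at percentile 63.0 of lists of equal brightness (median 0.20), although the same genes spread more between groups than most (1.09 against 0.30, median SD of the group means). RNA of one source would leave these genes no further apart between letters than other lists of equal brightness. Any percentile below the limit set for excluding one source could then occur. The percentile found lies above the middle and below that limit. The test thus gave no evidence against one source, and it did not exclude separate animals. Over all tested probe sets, differences between letters a and b had an SD of 0.43, 0.39, 0.38 and 0.49 log2 in the 4 groups. The 2 arrays of one sample, which lie on both sides of the lot line, differed with an SD of 0.36. Thus letters in spontaneous 100% and mechanical 21% differed little more than these 2 arrays. Letters in the other groups differed more. Whether letters a and b hold RNA of one source, such as one animal or one pool, or of separate animals stays open. If they do hold one source, the p-values of the report may measure array noise alone.

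For the fits of 1 factor, chance could not be excluded by the share of splits, but the splits that reached the real counts were those along the other factor or the lot line. Ventilation called 5 probe sets, and 3 of the 35 splits of the 8 samples into 4 and 4 gave as many, with 416 the highest of the others. Oxygen called 63, and 2 of 35 splits gave as many, with 416 again the highest of the others. The split that gave 416 follows the lot line, which is also the interaction. Because it exceeded both real counts, the share of splits could not have excluded chance for either factor. A fit of 1 factor leaves the other effects in the error, so the distance between these counts does not measure the effects. With all groups in the fit the interaction called 1439 probe sets, oxygen 1310 and ventilation 477. Only 3 splits keep the groups whole, and the 32 others, which divide pairs of like samples, called 0.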

How the results depend on the processing

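The fits within levels or within arrays and without the brightest probe sets were chosen after the data were seen. Counts within 1.5 times the reported one are not repeated here, which covers quantile normalization, cyclic loess, both offsets, the stricter filter, the second array alone and the 2 arrays as separate samples. Like counts did not always mean the same probe sets. Of the reported calls, quantile normalization kept between 58.5% (ventilation averaged over oxygen) and 91.9% (oxygen under spontaneous breathing). Cyclic loess kept between 60.2% (ventilation at 100%) and 95.9% (ventilation at 21%). Without the filter on low signal the counts were 247 for ventilation averaged over oxygen, 745 for oxygen averaged over ventilation, 490 for ventilation at 21%, 796 for ventilation at 100%, 540 for oxygen under spontaneous breathing and 397 for both factors together. With only the first array of the averaged sample the count was 256 for ventilation averaged over oxygen. With the letter as a replicate block the count was 308 for ventilation averaged over oxygen. Without the variance trend the count was 245 for ventilation averaged over oxygen. At an adjusted p under 0.10 the counts were 872 for ventilation averaged over oxygen, 1206 for ventilation at 21% and 1357 for oxygen under spontaneous breathing. In the fit of 1 factor the counts were 5 for ventilation averaged over oxygen and 63 for oxygen averaged over ventilation. With the lot line as a block the counts were 106 for ventilation at 21%, 470 for ventilation at 100%, 121 for oxygen under spontaneous breathing, 898 for oxygen under mechanical ventilation and 151 for the interaction. With only the groups compared the counts were 473 for ventilation at 21%, 574 for oxygen under spontaneous breathing and 503 for both factors together. With the brightest 10% left out the counts were 229 for ventilation averaged over oxygen, 827 for oxygen averaged over ventilation, 875 for ventilation at 100% and 334 for both factors together. At 21% oxygen only the count was 760 for ventilation averaged over oxygen. At 100% oxygen only the count was 1413 for ventilation averaged over oxygen. Within the arrays without the lot line the counts were 497 for ventilation at 100% and 933 for oxygen under mechanical ventilation. The fit with the lot line counts the 2 arrays of a sample apart, which without the block gave 895, 1704, 1029, 2138 and 1631 for the same contrasts. Fits with fewer samples or a term more have wider errors, the looser threshold admits more by construction, and for the other moves the cause was not tested.

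Each sample left out in turn gave counts of 128 to 518 for ventilation averaged over oxygen, 639 to 1126 for oxygen averaged over ventilation, 216 to 701 for ventilation at 21%, 464 to 1423 for ventilation at 100%, 364 to 794 for oxygen under spontaneous breathing, 956 to 1899 for oxygen under mechanical ventilation, 980 to 1318 for the interaction and 314 to 674 for both factors together, where the lone sample left in a group is assumed to vary like the others. The letters did not pair the samples: differences between letters a and b correlated at -0.13 to 0.07 between groups, and the replicate block moved no other count by over 1.5 times and ended no list call but that of the heat shock list for both factors together. List calls in the order of the report, from ventilation averaged over oxygen to both factors together, numbered 6, 7, 6, 6, 7, 11, 8 and 10 as reported, 1, 0, 0, 1, 0, 0, 0 and 0 with an estimated correlation, 15, 18, 17, 18, 13, 21, 20 and 16 with fry, which takes no account of genes outside a list, and between 5 and 8, 6 and 10, 5 and 7, 6 and 7, 6 and 7, 8 and 13, 7 and 9 and 7 and 10 with 1 sample left out. The correlation of the ventilation changes at the 2 oxygen levels was -0.22 with the offset of 1% and -0.35 with the lowest 60% left out.

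Among named genes with both factors averaged, log2 changes of the other sign stood at 100% oxygen alone for Il6 -0.13, Ccl2 -0.25, Col1a2 0.092, Thy1 -0.20 and Cd3g -0.25, at 21% oxygen alone for Icam1 -0.15, Plat -0.027 and Tnnc2 0.40, under mechanical ventilation alone for Ccl2 -0.036 and under spontaneous breathing alone for Ucp1 1.92. Only Ucp1 passed the threshold there, so no reversal was shown for the others. For both factors together the camera test of the cytoskeleton and adhesion list pointed up under quantile normalization with its median next to 0 but still negative (-0.0056), and the alveolar type 2 median was 0.013 there and 0.11 under cyclic loess, of the other sign, and the cause was not tested. Of the gene changes in the text, 2 lost their call under quantile normalization, 0 under cyclic loess, 12 without the filter, 16 with the lot line as a block and 44 in the fit of 1 factor, all with their direction kept. Between 18.4% and 20.01% of the probe sets of an array lay at or below 0, where no fold can be given. Signal over background limits the changes of weak genes, since the highest control probe set without a spiked target read between 171 and 302 on the arrays.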

Other observations

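RT1-Bb was looked at after its values were seen, and the test across genes was set before its counts were seen. The beta chain gene of the class II histocompatibility molecule RT1-B has 5 tested probe sets, and they moved apart with ventilation. The first had levels at or below 0 in all spontaneously breathing samples and 1117 ± 81.9 and 1371 ± 106 (SD, n = 2) in mechanically ventilated rats at 21% and 100% oxygen. A second stood near background, at 63.8 ± 14.7 and 31.5 ± 12.3 against 326 ± 27.3 and 274 ± 21.7, so its change is rough. The other 3 RT1-Bb probe sets had log2 changes of -0.45, -0.03 and -0.51, all below 0, which argues against a rise of the whole gene.

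Probe sets of a polymorphic gene that part in this way might come from rats with another RT1 type, such as another strain or colony, in the mechanical groups, and this would be confounded with ventilation. Outside RT1-Bb, a probe set parted by ventilation while the others of its gene did not in 2 of 872 genes with several probe sets, against 3 by oxygen and 2 along the interaction. No excess was found across genes, so whether the rats of the groups differed in descent stays open, as do a splice form and a difference between individual rats.

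Genes that cover more of the genome had higher interactions, a relation tested after it was seen. Over 3176 genes the interaction correlated with the log of the genomic span (Spearman rho = 0.33, and 0.29 under quantile normalization), and the median interaction was -0.16 in the shortest of 4 equal sets of genes and 0.53 in the longest. A difference between arrays with and without the lot line could give such a trend. The 2 arrays of the sample on both sides of that line differed with a rho of 0.031, in a test set before its value was seen. Its 95% bootstrap interval, -0.01 to 0.07, came from resampled genes of that single pair of arrays and does not measure the spread between samples. The 3' to 5' ratios of the control probe sets overlapped, at 1.08 to 1.29 with the line and 1.09 to 1.23 without it for GAPDH, and 0.96 to 1.15 and 0.95 to 1.03 for actin. The sample on both sides shares a single RNA, so a difference in RNA or its preparation along the lot line that these ratios do not show stays open beside a biological one.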
